A study of Mus musculus with 16 samples.

How the data were processed

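Polyadenylated RNA of mouse quadriceps muscle was sequenced in 16 libraries, 8 from animals with a skeletal-muscle-specific knockout of Nampt (KO) and 8 from wild-type animals (WT). Per the labels' protocols, RNA was extracted with Trizol and a column kit, libraries were made with the Universal Plus mRNA-seq kit, and paired-end reads of 52 bp were sequenced on an Illumina NovaSeq. Each library has an RNA integrity number (RIN) in the labels, between 8.2 and 8.8. Per the submitters' processing notes, bcl2fastq 4.0.3, STAR and Salmon were used with the mouse genome build GRCm38. The versions of STAR and Salmon, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited values are estimated counts per gene, as Salmon gives them, merged over transcripts by the authors and not scaled to depth. Of these values 11.1% were not whole numbers, and all were rounded to whole numbers before any count model.

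The table held 45706 genes. Totals per library ran from 16065394 to 51881258 estimated counts, with 26258709 ± 6979855 (SD, n = 8) in KO and 29556982 ± 10605144 (SD, n = 8) in WT. The number of table columns that matched no library was 0. The gene annotation GENCODE vM21 (GRCm38) was used only for coordinates and biotypes, and 99.5% of the tested gene identifiers matched it. A few symbols of the fixed lists were matched through the annotation's gene names, and 1 symbol had no match.

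Genotypes were taken from the labels. The labels name separate samples of each genotype without saying how many animals they came from, so p-values measure the spread between these samples. The labels give no sex, age or litter. Pairs of libraries within a genotype were compared for duplicates by a chi-square over genes with at least 20 counts. The smallest chi-square per degree of freedom was 8.09 in KO and 9.42 in WT, far above sampling noise, and all 16 libraries were kept as separate samples.

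KO and WT were compared gene by gene with edgeR 4.0.16 (R 4.3.3), using its quasi-likelihood F test, TMM normalization, the default low-count filter and no covariate. The filter left 13792 genes, and the genes removed held 0.0705% of all counts. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. CPM, each gene's count scaled to a common library size, were computed here from the deposited counts with TMM-scaled library sizes. Standard errors of log2 fold changes were taken from the fold change and its F statistic, and intervals are 95% intervals. The size of change the data still allow was described by counting genes whose interval lay inside a 1.5-fold change in either direction.

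Before the data were examined, 48 gene lists were fixed: pathways that use or make NAD, energy metabolism, proteostasis, muscle ageing, fibre types, other cell types of quadriceps and technical sets. For each list with at least 5 tested members, the mean of log2(CPM + 0.5) over members was taken per library. KO and WT were compared by an exact two-sided permutation test over all 12870 assignments, with Benjamini-Hochberg adjustment over 45 lists. The lists of lymphocyte, neutrophil and sex-linked genes had fewer tested members and were not tested. Nampt was left out of the score of its own list. Members of a list that passed an adjustment over the list alone are counted separately. Principal components 1 to 4 of the 2000 most variable genes were compared by the same exact test.

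Genes named in the text were chosen by a rule fixed before the data were examined. The rule takes Nampt, then called genes that are not gene models and reach a mean of 1 CPM, by fold change and by p. For each list it takes called members or, where there are none, up to 2 members with the highest mean CPM. Genes named outside that rule are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

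The gene test was tested on simulated counts for the KO and WT comparison, drawn from the real means, library sizes and dispersions, with 200 genes changed. Among 13680 genes in the simulation, 38% of the genes changed 1.25-fold were recovered, 80% of those changed 1.5-fold, and 100% of those changed 2-fold and 3-fold. Of the calls, 2.98% were unchanged genes, and 95.0% of the intervals held the true value. In the same simulation, a list shifted by 0.15 on the log2 scale was estimated at 0.14. The list test called 2 other lists there, each with 2 members among the genes changed singly, and 0 of the 29 lists without a changed member. The simulation draws genes independently of each other, so it does not include genes that vary together. Genes with the lowest levels were left out of the draw of changed genes. It made 168 calls against 6 in the real data, so its Benjamini-Hochberg cutoff was looser. At the cutoff of the real data the recovered shares can only be the same or lower.

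The alternatives were other normalizations, filters and covariates, DESeq2 1.42.0, limma 3.58.1 with sample quality weights, removal of each library in turn, and for lists other scores and set tests. A carry-over covariate and the removal of 4 KO libraries were added after seeing the data. The 16 libraries were also split in other ways into groups of 8, with 100 splits fitted, the real one included.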

Results

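Quadriceps muscle of mice lacking Nampt in skeletal muscle was compared with that of wild-type mice, in 8 KO and 8 WT libraries of polyadenylated RNA. NAMPT makes nicotinamide mononucleotide from nicotinamide and is the rate-limiting enzyme of the salvage route to NAD. The study's title asks whether a loss of NAD in skeletal muscle speeds muscle ageing. The comparison therefore covers the targeted gene, other genes of NAD metabolism, gene groups tied to muscle ageing, and the fibre and cell types that make up the tissue. Totals per library ran from 16065394 to 51881258 estimated counts, and the difference in mean total between KO and WT was within the spread between libraries (exact two-sided permutation p = 0.501, n = 8 each). The RIN was 8.61 ± 0.164 in KO and 8.56 ± 0.160 in WT (SD, n = 8 each; exact permutation p = 0.661).

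Nampt was lower in every KO library than in every WT library. It lay between 60.4 and 88.7 CPM in KO and between 125.5 and 161.1 CPM in WT, with means of 73.4 ± 9.30 and 141.4 ± 12.0 CPM (SD, n = 8 each). Its log2 fold change was -0.95 with a standard error of 0.07 (edgeR quasi-likelihood, adjusted p = 9.68e-07), which places KO at 51.9% of WT with a 95% interval from 46.7% to 57.7%. An exact two-sided permutation test of the log2 values gave p = 0.000155, the smallest that 12870 assignments allow. Nampt (ENSMUSG00000020572) is a protein-coding gene on chromosome 12 of GRCm38, from 32819545 to 32853349 on the plus strand. Estimated counts sum over all exons of a gene, so they do not show which part of the transcript was deleted. The long non-coding gene Gdap10 lies inside Nampt on the same strand, with a log2 fold change of 0.72 and an adjusted p of 0.457.

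Esr1, which encodes oestrogen receptor alpha, rose in KO by the largest fold of any called gene. It lay between 608.5 and 985.6 CPM in KO and between 20.7 and 34.8 CPM in WT, with means of 768.6 ± 131 and 26.4 ± 5.55 CPM (SD, n = 8 each). The log2 fold change of Esr1 was 4.86 with a standard error of 0.14, a 29.1-fold difference (adjusted p = 9.69e-14), and its lowest KO library was 17.5 times its highest WT library. Esr1 (ENSMUSG00000019768) spans 4611593 to 5005614 on the plus strand of chromosome 10. The 6 tested genes nearest to Esr1 on that chromosome, 3 on each side, had log2 fold changes between -0.21 and 0.15, and 0 of them passed the test. Estimated counts per gene do not show which exons of Esr1 the reads cover.

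**Figure D1:**
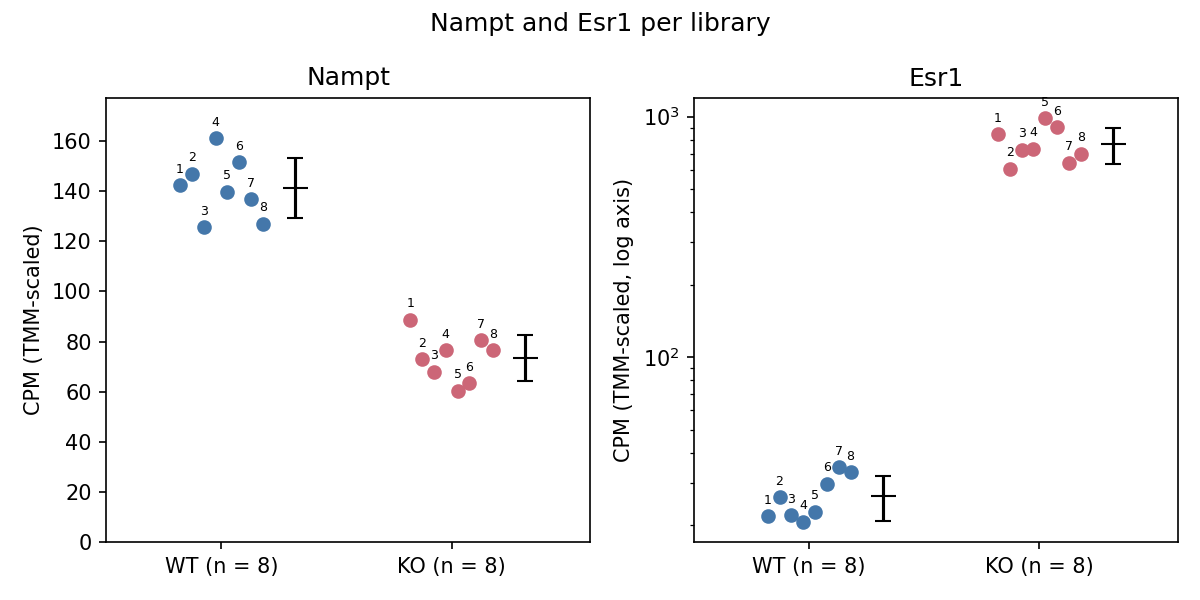
CPM of Nampt (linear axis) and Esr1 (log axis) in each library, with the replicate number above each point and the group mean with SD at the right of each group. The KO libraries lie between 60.4 and 88.7 CPM for Nampt and at or above 608.5 CPM for Esr1, with no overlap with WT for either gene.

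Across the 13792 tested genes, 6 passed the test, 3 higher and 3 lower in KO. Besides Nampt and Esr1 they were Actr3b, Trp63, Gm16124 and Gm11613. Actr3b, a subunit of the actin-nucleating ARP2/3 complex, fell from 18.96 ± 2.14 to 13.1 ± 1.98 CPM (SD, n = 8 each; log2 fold change -0.54, standard error 0.09, adjusted p = 0.0464). Trp63, a transcription factor of the p53 family, fell from 9.21 ± 1.35 to 6.67 ± 0.399 CPM (log2 fold change -0.46, standard error 0.08, adjusted p = 0.0471). The gene models Gm16124 and Gm11613, named here after their values were seen, rose by 0.72 and 0.52 on the log2 scale (adjusted p = 0.0471 for both), from 1.26 and 3.29 CPM in WT. Gm16124 lies antisense to Cul5 on chromosome 9, and the length of any overlap was not measured. Without a stated strand setting, reads from bases that both genes share cannot be told apart. The log2 fold change of Cul5 was -0.10 (adjusted p = 0.535). In each of these 4 genes all 8 KO libraries lay on one side of the WT mean.

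**Figure D2:**
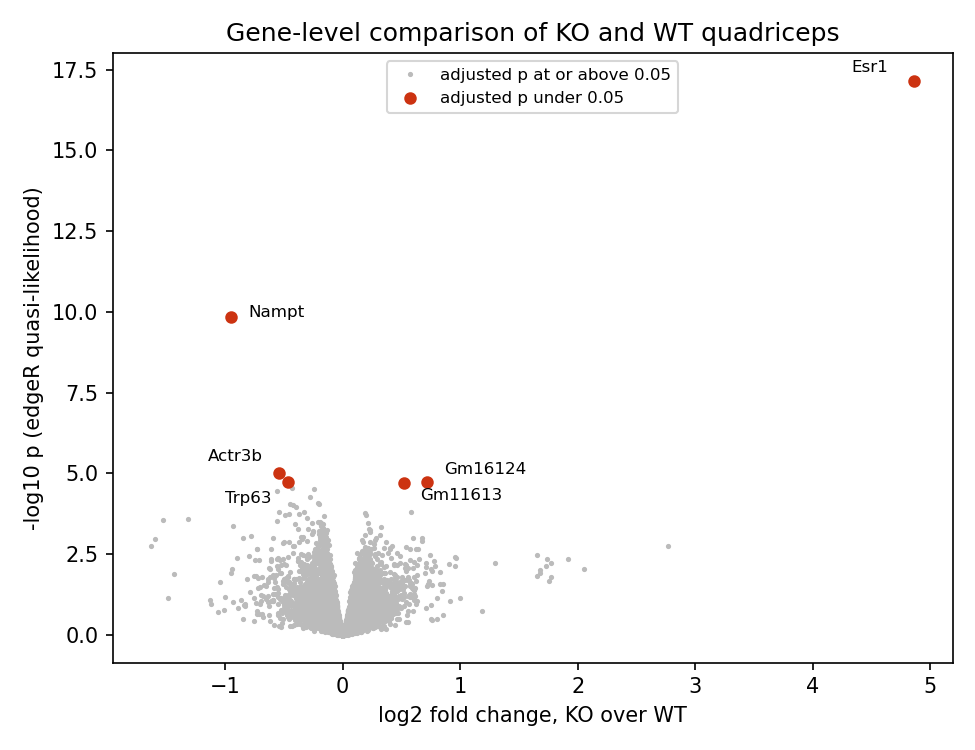
Log2 fold change of KO over WT against -log10 of the edgeR p for the 13792 tested genes, with the 6 called genes in red and named. Esr1 and Nampt lie apart from the others, with log2 fold changes of 4.86 and -0.95.

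Actr3b is at 25759997 to 25850688 on the plus strand of chromosome 5, Trp63 at 25683763 to 25892102 on the plus strand of chromosome 16, Gm16124 at 53667246 to 53681265 on the plus strand of chromosome 9, and Gm11613 at 97644184 to 97660367 on the minus strand of chromosome 11. Only Nampt and Esr1 passed in every alternative fit that was run. The number of called genes ranged from 2 under 2 of the 3 other scalings, the replicate block or a carry-over covariate to 17 with limma (3 higher, 14 lower) and 102 with DESeq2 (16 higher, 86 lower), and it was 2 without 4 KO libraries that carried more RNA without a poly(A) tail. At an unadjusted p under 0.05, 1320 genes were counted, 555 higher and 765 lower, where 690 are expected by chance. Counts at this p in the gene lists below are to be read against 1320 of the 13792 tested genes.

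Of the genes of NAD synthesis and salvage, 17 of 26 were measured, and Nampt was the 1 member that passed over all genes. The score of the other members was 0.12 higher in KO on the log2 scale (95% interval 0.04 to 0.20, exact two-sided permutation p = 0.00777, adjusted p = 0.339, n = 8 each), which did not pass over the 45 lists. Of those 16 members 8 had log2 fold changes above 0, with a median of 0.00, and a score taken as the median over members differed by 0.01 instead of 0.12. Adjusted over the list alone, 3 members passed, Nampt lower and Nmrk2 and Kmo higher, the last 2 at 0.0482 each. That adjustment counted Nampt, the targeted gene, whose small p eases the bar for the other members. The passes of Nmrk2 and Kmo rest on its inclusion, so they are not evidence of a rise in these genes. Nmrk2, named after its values were seen, encodes a muscle kinase that makes nicotinamide mononucleotide from nicotinamide riboside, and had 241.0 CPM in KO and 124.2 CPM in WT. Its log2 fold change was 0.95 with a standard error of 0.32 (adjusted p = 0.307 over all genes, 0.0482 over the list), and 7 of 8 KO libraries lay above the WT mean. Kmo, of the kynurenine route from tryptophan to NAD and also named after its values were seen, had a log2 fold change of 0.60 at a low level of 0.703 CPM in KO and 0.446 CPM in WT (adjusted p = 0.318 over all genes).

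Among 28 NAD-consuming enzymes, 0 passed over all genes in the edgeR fit, and 1, Art3, passed with adjustment over the list alone. Art3 is a member of the ADP-ribosyltransferase family and was named after its values were seen. Whether its product uses NAD was not tested. Art3 had a log2 fold change of -0.28 with a standard error of 0.05 (adjusted p = 0.0752 over all genes), and was the 1 member called by DESeq2 and by limma. Without WT library 7 it passed with edgeR as well (adjusted p = 0.0427), and over the 28 alternative fits its adjusted p ran from 0.000616 to 0.234. In the edgeR fit 4 members had an unadjusted p under 0.05. The members with the highest CPM, Art1 and Tnks2, had log2 fold changes of 0.00 and -0.09. The score of the list differed by 0.02 (95% interval -0.01 to 0.06, exact permutation p = 0.204). Of the 13 measured genes of nicotinamide and methyl-donor metabolism 0 passed with edgeR, DESeq2 or limma, with 0 at an unadjusted p under 0.05. Mat2a, which makes S-adenosylmethionine, had a log2 fold change of -0.18. DESeq2 gave no adjusted p for 5 of these 13 genes, nor for 13 of the 28 NAD-consuming enzymes.

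Genes of energy metabolism, 200 in 8 lists, gave 0 called members with edgeR, DESeq2 or limma, with 9 at an unadjusted p under 0.05 in the edgeR fit. DESeq2 gave no adjusted p for 4 of the 200. The nuclear-encoded genes of complex I numbered 37, and all 37 had intervals inside a 1.5-fold change, with a score difference of -0.01 (95% interval -0.09 to 0.06). Ndufs1, a core subunit of complex I, had a log2 fold change of -0.02. The 28 genes of complexes II to IV had a score difference of 0.02 (95% interval -0.06 to 0.11), with Sdha at 0.09 and Uqcrc1 at 0.00. Of the 13 mitochondrially encoded mRNAs, 12 had log2 fold changes below 0, and the score difference was -0.10 (95% interval -0.31 to 0.11, exact permutation p = 0.301). It was -0.06 without KO library 3 and -0.17 without KO library 2. The most abundant of them, mt-Co1 and mt-Cytb, had log2 fold changes of 0.00 and -0.00. For glycolysis (25 genes), with Aldoa at -0.05 and Gapdh at 0.03, the score differed by 0.02 (95% interval -0.04 to 0.08). For fatty acid uptake and oxidation (38 genes), which holds Pdk4 and Lpl, it differed by -0.07 (95% interval -0.30 to 0.17), and by 0.01 without WT library 7. Its sign also turned, to 0.07, without KO libraries 1, 3, 5 and 8, and with the carry-over covariate the difference was -0.00.

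Processes tied to muscle ageing were described by 8 lists. Of their 200 tested genes 0 passed over all genes with edgeR. At an unadjusted p under 0.05 there were 17 of the 200, against 1320 of all 13792 tested genes. DESeq2 called 2 of the 200, Mstn (adjusted p = 0.00299) and Ei24 (adjusted p = 0.0473), both lower in KO, and limma called Mstn alone (adjusted p = 0.0381). DESeq2 gave no adjusted p for 69 of the 200. Over the 28 alternative fits the adjusted p ran from 0.00299 to 0.276 for Mstn and from 0.0473 to 0.491 for Ei24. Intervals inside a 1.5-fold change were found for 148 of the 200 (74%), against 86.2% of all 13792 tested genes. The score of atrophy-associated ubiquitin ligases and FOXO targets differed by -0.06 (95% interval -0.18 to 0.06, exact permutation p = 0.299), and by -0.03 without WT library 7. Fbxo32 and Fbxo40, muscle ubiquitin ligase genes, had log2 fold changes of -0.04 and 0.02. In that list Mstn, which encodes the growth inhibitor myostatin and is named after its values were seen, passed with adjustment over the list alone, at a log2 fold change of -0.49 with a standard error of 0.11 (adjusted p = 0.12 over all genes). Without WT library 7 it passed over all genes with edgeR as well (adjusted p = 0.0462). The denervation response list (28 genes, among them Nos1 at 0.02) differed by 0.03 (95% interval -0.17 to 0.24), by 0.12 without WT library 4 and by 0.01 without KO library 4. The regeneration and embryonic myosin list (20 genes) differed by 0.14 with the widest interval of the ageing lists, -0.27 to 0.56. It differed by 0.29 without WT library 4 and by 0.06 without KO library 4, and H19 had a log2 fold change of 0.51 (adjusted p = 0.457).

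The p53 and DNA damage response list differed by -0.05 (95% interval -0.12 to 0.02, exact permutation p = 0.13). Adjusted over the list alone, 3 of its 26 members passed, all lower, namely Phlda3 at -0.26, Ei24 at -0.12 and Polk at -0.42 on the log2 scale, the last 2 named after their values were seen. Over all genes their adjusted p were 0.272, 0.273 and 0.26. The list of senescence and secretory genes (22 genes, with Igfbp5 and Hmgb1 at -0.04 and -0.05) differed by 0.01 (95% interval -0.21 to 0.23), by -0.04 without KO library 2 and by 0.07 without WT library 3. The interferon list (32 genes) differed by 0.10 (95% interval -0.10 to 0.31), and by 0.06 without KO library 2, with 25 of its members above 0. Inflammation, NF-kB and complement (24 genes, with C3 at -0.01) and extracellular matrix and fibrosis (33 genes, with Col3a1 at 0.13 and Dcn at -0.05) differed by 0.04 and 0.03, with intervals of -0.20 to 0.28 and -0.26 to 0.31. Without WT library 8 both turned, to -0.01 and -0.03, and without KO library 7 they were 0.09 for each. Col3a1 ran from 0.01 to 0.23 when 1 library was left out, and was 0.03 with limma, and Dcn from -0.09 to 0.01.

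The 32 genes of both fibre type lists gave 0 called genes with edgeR, DESeq2 or limma, with 4 at an unadjusted p under 0.05 in the edgeR fit. DESeq2 gave no adjusted p for 3 of the 32. The slow fibre contractile list (15 genes) had a score 0.29 higher in KO with an interval from -0.14 to 0.73 (exact permutation p = 0.173), and 0.17 higher without WT library 8. Of its members 14 had log2 fold changes above 0. Myh7 and Atp2a2, the slow myosin heavy chain and slow calcium pump, had log2 fold changes of 0.31 and 0.18, and of 0.15 and 0.08 without WT library 8. Leaving out 1 library at a time gave up to 0.49 for Myh7, without WT library 5, and up to 0.29 for Atp2a2, without WT library 1. Myh7 was at 0.58 in the replicate block fit and 0.57 with the carry-over covariate, and Atp2a2 at 0.34 with that covariate. The fast fibre contractile list (17 genes), led by Myh4 at 70670 CPM in KO and 74475 CPM in WT, differed by -0.03 (95% interval -0.10 to 0.03). The excitation-contraction coupling and calcium handling list (30 genes, among them Ryr1 at -0.01 and Atp2a1 at -0.05) differed by -0.04 (95% interval -0.07 to -0.00, exact permutation p = 0.0326, adjusted p = 0.49). Polyamine and amino acid catabolism (25 genes) differed by -0.08 (95% interval -0.14 to -0.02, exact permutation p = 0.0151, adjusted p = 0.339). In that list Smox and Amd1, of polyamine metabolism, had log2 fold changes of -0.65 and -0.46, and Amd1 has a near-identical copy with which it can share reads.

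Of 138 markers of other cell types in the tissue, 0 were called with edgeR or limma. In the edgeR fit 14 had an unadjusted p under 0.05, against 1320 of all 13792 tested genes. With DESeq2 1 marker, Notch3, was called higher in KO (adjusted p = 0.00393, with a range up to 0.245 over the 28 alternative fits). DESeq2 gave no adjusted p for 49 of the 138. Endothelial markers were 0.10 higher in KO (95% interval 0.00 to 0.20, exact permutation p = 0.0449, adjusted p = 0.505), with 14 of 16 members above 0 and Cdh5, the endothelial cadherin, at 0.18. Pericyte and smooth muscle markers were 0.07 higher (95% interval -0.01 to 0.14, exact permutation p = 0.0692). Adjusted over the list alone, 3 of those 12 markers passed, Notch3 at 0.20, Pdgfrb at 0.16 and Cspg4 at 0.23, named after their values were seen. Macrophage, satellite cell and fibro-adipogenic markers differed by 0.09, 0.04 and 0.01, with intervals of -0.30 to 0.47, -0.04 to 0.13 and -0.19 to 0.21. Without 1 library the macrophage difference ran from 0.02 (WT 8) to 0.17 (WT 4), the satellite cell difference fell to 0.02 (KO 4), and the fibro-adipogenic difference ran from -0.03 (WT 8) to 0.06 (KO 7) and turned its sign without any 1 of 6 libraries.

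**Figure D3:**
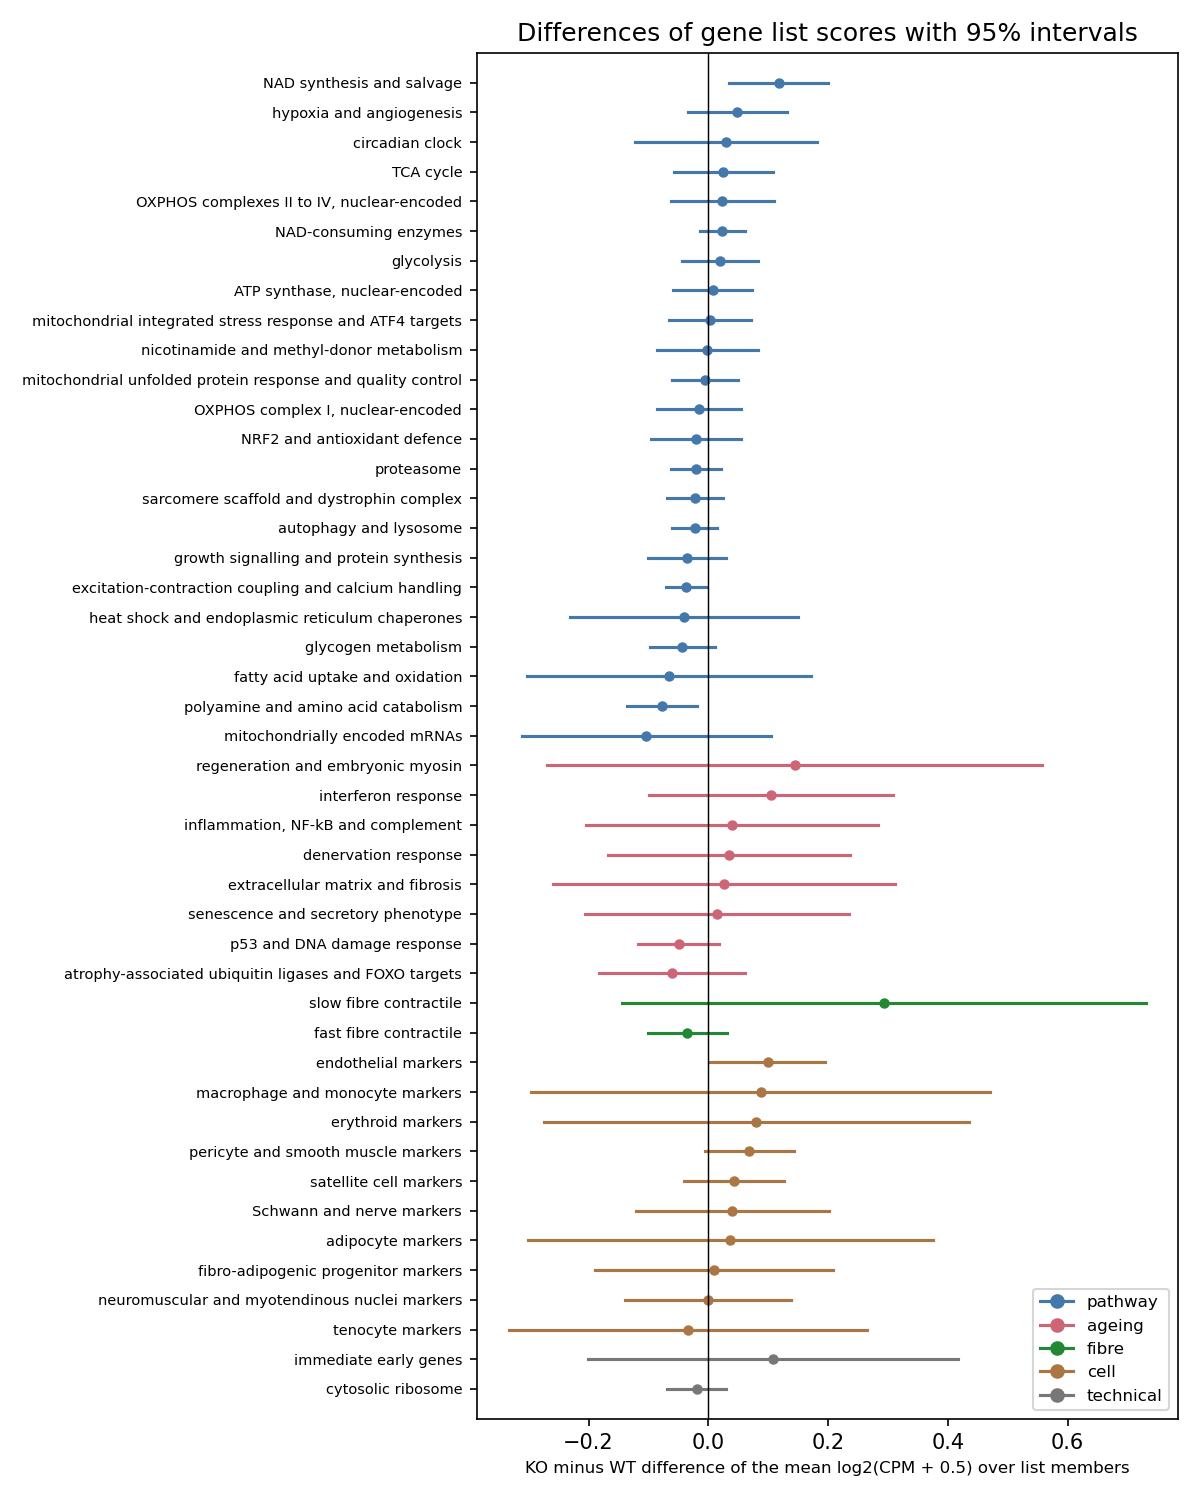
Difference of the mean log2(CPM + 0.5) over list members, KO minus WT, for the 45 tested gene lists, as points with 95% intervals from 8 libraries per group and coloured by kind of list. The NAD synthesis and salvage list lies at 0.12, and 0 of the 45 lists passed the exact permutation test after adjustment.

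Of the 45 lists 0 were called by the exact permutation test, with 4 at an unadjusted p under 0.05. Leaving out each library in turn turned the sign of the score difference in 17 of the 45, and in 38 of the 45, these included, at least 1 library turned it or moved it by over 1.5 times. Without the 4 KO libraries rich in RNA without a poly(A) tail, the lists of mitochondrially encoded mRNAs, fatty acid uptake and oxidation, and atrophy-associated genes turned to 0.00, 0.07 and 0.01, and the endothelial and pericyte lists differed by 0.16 and 0.12. With the carry-over covariate the slow fibre list differed by 0.46. With the median over members the regeneration list differed by 0.39 and the polyamine list by -0.03. The set test fry called 0, and camera called 3 with a preset correlation of 0.01 (slow fibre contractile and endothelial markers higher, excitation-contraction coupling lower). With an estimated correlation camera called 0, with adjusted p of 0.887, 0.585 and 0.585 for those 3. On principal components, the first 4 held 17.5%, 10.9%, 9.78% and 9.08% of the variance of the 2000 most variable genes. KO and WT differed on component 2 by an exact permutation p of 0.0186, adjusted p = 0.0746 over the 4, and 0 components were called. Esr1 had the largest weight of all genes at the KO end of component 2, so that difference draws in part on Esr1.

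RNA that lacks a poly(A) tail differed between libraries. In KO libraries 1, 3, 5 and 8 the 7SK RNA gene Rn7sk lay between 19.99 and 34.4 CPM, against 1.95 to 5.05 CPM in the other 4 KO libraries and 1.12 to 15.8 CPM in WT. Yam1, a locus that collects reads like ribosomal RNA, took 2.27% to 2.45% of all counts in those 4 libraries, and 0.164% to 0.438% in the other KO libraries. The mean log2 level of 6 such RNAs was 1.47 higher in KO than in WT, within the spread between libraries (exact permutation p = 0.0824, n = 8 each).

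**Figure D4:**
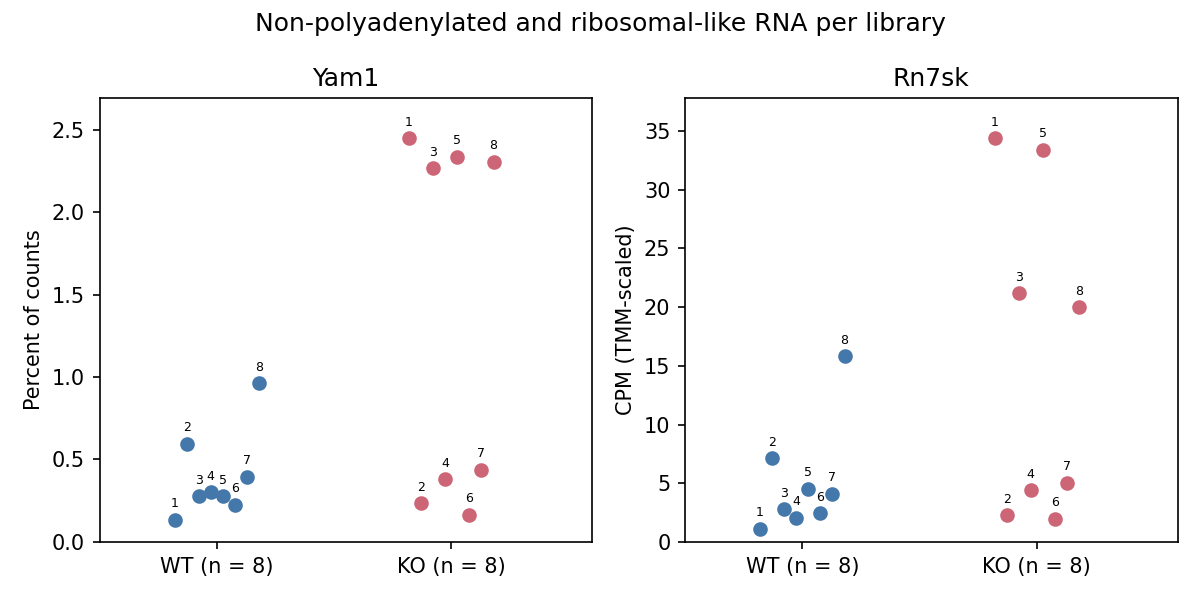
Share of counts assigned to Yam1 (percent) and CPM of Rn7sk in each library, with the replicate number above each point. KO libraries 1, 3, 5 and 8 lie above every WT library, and WT library 8 lies highest of the WT libraries, at 0.961% for Yam1.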

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

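Single libraries were compared with the other 7 of their group by the gap to the nearest library over the range of the group, for 111 values in KO and in WT. Of these 222 groups 7 held such a library, and chance gives about 11. WT library 7 stood apart in 3 values. Its Pdk4 level was 1358 CPM against 187.6 to 555.0 CPM in the other WT libraries, Eef2k was 78.8 CPM against 85.8 to 91.8, and its score for NRF2 and antioxidant defence genes was 5.40 against 5.13 to 5.24. WT library 4 stood apart in the score of the denervation response, at 3.75 against 3.03 to 3.23, and in that of regeneration and embryonic myosin, at 4.55 against 3.19 to 3.62. WT library 3, the deepest library, had 459.4 CPM of Dcn against 296.5 to 366.6. KO library 2, the shallowest library, had 25441 CPM of Atp2a1 against 28862 to 30675 in the other KO libraries.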

How the results depend on the processing

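The carry-over covariate and the removal of KO libraries 1, 3, 5 and 8 were chosen after seeing the data. Nampt and Esr1 kept their direction and stayed past the threshold in all 28 alternative fits, with log2 fold changes of -0.99 to -0.91 and 4.77 to 4.93. The count of 6 changed genes was 2 with relative log expression factors, with library size only, with the carry-over covariate and in the 12 libraries left, 3 with no low-count filter, 17 with limma and 102 with DESeq2. Requiring a log2 fold change of at least 1 as well left 1, Esr1, because Nampt lies at -0.95. Without 1 library the count ran from 2 to 8. It was 2 without KO 2, 3, 5 or 8 or WT 3, 4, 5, 6 or 8, and 3 without KO 1 or WT 2. In the replicate block fit the count was 2. The labels do not say whether the replicate numbers pair the samples. Same-numbered KO and WT libraries correlated by -0.10 to 0.24 in their deviations, 3 of 8 above 0.1. Of the 8 numbers, 2 correlated best with their own number. Such correlations cannot exclude a pairing, so it stays open. Actr3b, Trp63, Gm16124 and Gm11613 kept their sign in all fits but passed in 10, 5, 6 and 5 of the 28. DESeq2 gave no adjusted p for Gm16124 and Gm11613, which is counted here as not passed. For gene lists, 0 were called in 24 of 27 alternatives, camera with a preset correlation called 3, and leaving out 1 library gave 0 to 1. Without KO 3, pericyte and smooth muscle markers passed (adjusted p = 0.035), and without KO 5, excitation-contraction coupling passed (adjusted p = 0.049). With the 500 most variable genes 1 principal component passed (adjusted p = 0.0448). The share of Esr1 in that component was not examined. With the narrower alternative margin, 0.32 on the log2 scale in either direction, 70 of the 200 ageing genes (35%) had intervals inside it, against 62.6% of all tested genes. For every change above, the cause was not tested beyond the threshold of fold change. In the simulation, at a looser cutoff than in the real data, 38% of the smallest changes were recovered. Changes of that size can thus be missed.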

Other observations

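In the list of growth signalling and protein synthesis (28 genes) 0 passed over all genes with edgeR. There 9 of the 28 had an unadjusted p under 0.05, against 1320 of all 13792 tested genes. DESeq2 and limma each called 1, Mstn, and DESeq2 gave no adjusted p for 4 of the 28. Adjusted over the list alone, 4 members passed, 3 lower and 1 higher, all named after their values were seen. Mstn had 39.0 ± 6.17 CPM in KO and 54.8 ± 8.70 CPM in WT (SD, n = 8 each), Rheb and Eef2k had log2 fold changes of -0.13 and -0.14, and Gdf11, a close relative of myostatin, had one of 0.46 (edgeR adjusted p = 0.258 over all genes), which was 0.25 with the carry-over covariate and 0.22 without KO libraries 1, 3, 5 and 8 (adjusted p = 0.508 and 0.693). The score of the whole list differed by -0.04 (95% interval -0.10 to 0.03). Outside that list, Wfikkn2 and Stk26, also named after their values were seen, had log2 fold changes of -0.43 and -0.56 and lay close to the threshold (edgeR adjusted p = 0.0541 and 0.0547). Both passed with limma and without WT library 7, and all 8 genes with an adjusted p between 0.05 and 0.1 were lower in KO.

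Protein turnover and translation lists moved little. The proteasome list (31 genes) differed by -0.02 (95% interval -0.06 to 0.02), autophagy and lysosome (29 genes, with Sqstm1 at -0.04 and Ctsd at -0.12) by -0.02 (-0.06 to 0.01) and the cytosolic ribosome (33 genes) by -0.02 (-0.07 to 0.03), and in each list all members had intervals inside a 1.5-fold change. The list of the mitochondrial integrated stress response and ATF4 targets (34 genes, with Gpt2 at -0.36 and Vldlr at -0.09) differed by 0.00 (-0.07 to 0.07), and that of mitochondrial quality control by -0.01. Heat shock and endoplasmic reticulum chaperones differed by -0.04, the circadian clock by 0.03, hypoxia and angiogenesis by 0.05, NRF2 and antioxidant defence by -0.02, and immediate early genes by 0.11 (-0.20 to 0.42; 0.06 without WT 8 and 0.19 without WT 7). The TCA cycle differed by 0.03, ATP synthase by 0.01, glycogen metabolism by -0.04, nicotinamide and methyl-donor metabolism by -0.00, and the sarcomere scaffold and dystrophin complex by -0.02. Markers of adipocytes, erythroid cells, Schwann cells and nerve, tenocytes and neuromuscular and myotendinous nuclei differed by 0.04, 0.08, 0.04, -0.03 and -0.00, and each of these 5 differences turned its sign without at least 1 library. In 10 tested lists the median log2 fold change and the score difference, both without Nampt, had opposite signs. The Y-linked gene Ddx3y was detected at 25.8 to 47.7 CPM in all 16 libraries, and Xist at 0 to 6 counts.

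The tests of an Esr1 transgene, of swapped Nampt libraries, of the genotype as source of RNAs without a poly(A) tail and of RNA degradation were chosen after the result was seen. As a hypothesis, the Esr1 signal in KO may come from a Cre recombinase fused to an oestrogen receptor domain, whose reads would be counted as Esr1. The lowest KO library was 17.5 times the highest WT library, which such a transgene would give, but the labels name no Cre line and counts per gene do not separate exons, so this cannot be told apart from expression of the endogenous gene. Raised activity of the receptor was examined in 18 tested oestrogen receptor target genes. Their mean log2 level was 0.0319 higher in KO (95% interval -0.05 to 0.12, exact permutation p = 0.457, n = 8 each), and 0 passed the gene test. The interval ends below a 1.2-fold rise, which argues against a larger mean rise of these 18 genes. No sample here shows that they respond to the receptor in this muscle, so its activity stays open.

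Nampt stayed at 51.9% of WT in KO. A swapped or mislabelled library is argued against, since the highest KO library was 0.707 times the lowest WT library, a gap of 36.8 CPM against a larger group SD of 12.0 CPM. The remaining transcripts may come from cells other than muscle fibres, or from transcripts that lack the deleted part, which was not tested. Within the 8 KO libraries, Nampt correlated with the score of endothelial, fibro-adipogenic and macrophage markers by Pearson r = -0.15 (exact permutation p = 0.717) and Spearman rho = -0.07 (exact permutation p = 0.882), and by r = -0.43 without the 2 libraries farthest from the median of that score. This was 1 relation tested, and at 8 libraries it leaves the first explanation open.

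RNAs without a poly(A) tail were high in KO libraries 1, 3, 5 and 8. In the mean log2 level of 6 such RNAs, 4 of the 8 KO libraries lay above the highest WT library, and the other 4, at 1.34 to 3.12, lay within the WT range of 1.09 to 4.60. The pattern was seen in these same RNAs, so the count does not test an effect of the genotype, which stays open. Of the 4 libraries 0 had a RIN below every other KO library, with 8.4 to 8.8 in both sets. That count was fixed by values already seen, so it is not a test. The RIN was 8.7, 8.8, 8.7 and 8.4 in KO 1, 3, 5 and 8. It was 8.6, 8.8, 8.5 and 8.4 in KO 2, 4, 6 and 7. More degraded RNA is thus argued against only as far as the RIN shows it. Carry-over of such RNA in library preparation may be the source and stays open too. In 16 other genes of classes taken to lack a tail, mostly histone genes, 3 of the 4 libraries lay above every other KO library. The levels (2.05 to 2.26 on the log2 scale, against 1.72 to 2.20 and, in WT, 1.76 to 2.37) overlapped. Whether these histone transcripts lack a tail in this tissue was not shown, and the set held Hist1h1c at 134.2 CPM and Hist1h2bc at 42.4 CPM. It therefore does not decide on carry-over.

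Other splits of the 16 libraries into 8 and 8 were fitted, 100 in all with the real one. A count of at least 6 changed genes was found in 2 of the 100, the real split included, a share under 0.05. The 6 hold Nampt, the targeted gene, and Esr1, so this count does not exclude chance for the other 4. The real split also has KO 1, 3, 5 and 8 on one side, and the drawn splits were not matched for this. With the carry-over covariate only Esr1 and Nampt were called. Over the 28 alternative fits log2 fold changes ran from -0.59 to -0.48 for Actr3b and from -0.50 to -0.41 for Trp63. For Gm16124 and Gm11613 they ran from 0.60 to 0.77 and from 0.48 to 0.58. A call near the threshold can also be lost through lower power alone. The lost calls therefore do not decide whether the 4 genes come from that imbalance, and they are not separated from it. The 4 genes besides Esr1 and Nampt were likewise matched in 2 of the 100, with 39 in the highest other split. That split called many more genes than the real one, with KO 2, 4, 5, 6, 7 and 8 and WT 7 and 8 on one side, which points to a structure of the samples. What that structure is was not tested, and with 6 KO and 2 WT libraries on one side it is not separate from genotype. The 1320 genes with an unadjusted p under 0.05 were reached in 10 of the 100, with 1899 in the highest other split, so chance is not excluded for that count.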
